A study of Sus scrofa with 12 samples.

How the data were processed

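Ileal samples of 12 arrays were analysed, 3 from each combination of condition and site. The conditions were infection with porcine circovirus type 2 (PCV2), sampled 21 days after infection, and no infection. Per the labels the tissue of the inductive site was Peyer's patches and mesenteric lymph nodes and that of the effector site epithelium and lamina propria, and it is not stated whether each sample holds both tissues of its site. Per the labels, total RNA was extracted with TRIzol, checked for its integrity number, purified on columns with DNase, amplified and labelled with Cy3, and each array was hybridised with 1 sample. Each experiment at a site is described as using another donor, and the labels do not say whether equal numbers at the 2 sites are one piglet.

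The deposited scanner files, 1 per array, hold intensity values for each spot, and the columns used were the processed signal, the mean signal, the local background median and the flags. Per the file headers, Feature Extraction 10.7.3.1 subtracted the background and removed spatial trends within each array, with no step between arrays. The submitters' processing notes name Agilent Feature Extraction 10.7 and limma, without a version for limma. The flags, per the file headers, are of another kind, 0 or 1 per spot, for signal well above background, saturation and outliers. The authors' deposited series matrix holds log2 values with nearly the same distribution on all 12 arrays (medians from 5.5544 to 5.5547), that is, quantile-normalized values. For each array they correlated across probes with log2 of the scanner signal at r = 0.9988 or above, and the matrix served here as an alternative only.

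Spots flagged as controls or outliers were left out. The log2 processed signal of each spot was averaged over the spots of a probe, and the 75th percentile of each array was subtracted. A probe was tested when it lay well above background on at least 3 of the 12 arrays, counted without regard to group. Of 43603 probes, 31851 met this, 6 of them were lost to outlier flags and 31845 were tested. Gene symbols came from the annotation in the files and from a table of porcine gene names. Of the 43603 probes, 13858 received a symbol and 29745 did not, and the tested probes covered 5892 named genes. A gene is represented by its probe with the highest mean log2 signal over the 12 arrays.

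The test was limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays, 8 residual and 2.50 prior degrees of freedom, empirical Bayes moderation and Benjamini-Hochberg adjustment over probes, with a threshold of 0.05. Standard errors in the text are those of this model. The 5 comparisons were infected minus control at each of the 2 sites, the difference between these differences (effector minus inductive), and inductive minus effector in control and in infected piglets. Before the data were examined, 31 lists of genes for cell types, tissue layers and pathways were fixed, along with the comparisons, the filter, the rule for naming genes and all alternatives except the one named below. The lists were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists of a comparison, and a list needed at least 5 measured genes. Camera was repeated with an estimated correlation, and fry tested each list without comparing it with other genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

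Genes are named by 3 criteria. The first takes the 12 largest positive and 12 largest negative differences past the threshold (8 and 8 for the comparisons of sites) whose groups of arrays do not overlap and which are above background on all arrays of the higher group. Where fewer than 5 pass in a direction, it takes the 8 genes with the smallest p in that direction, reported as not past the threshold. The second takes the 3 members with the smallest p in each list, and the third is a fixed set of immune and epithelial genes. JCHAIN and CLDN1 belong to that set and were not tested here. Where all probes of a gene lay below background on every array of a group, the difference is given as a lower bound against the background limit, and no fold is given where both groups lay there or where that bound is under 1.

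Signal at the 75th percentile ran from 288.6 to 454.3 intensity units and the share of spots well above background from 63.7% to 72.5%, with 0 saturated spots on any array. The number of arrays, 3 per group, limits the precision. The file headers place the arrays on 3 slides of 4. The first slide holds control replicates 1 and 2 from both sites, the second holds infected replicate 1 and control replicate 3 from both sites, and the third holds infected replicates 2 and 3 from both sites. Infection can therefore be compared within a slide only on the second, with 1 piglet against 1, and a model with slide as a fixed block draws the infection difference averaged over the sites from that slide and the difference between the sites from all 12 arrays. This model takes the 2 sites of a piglet as separate samples, so its p for infection is too small if equal numbers are one piglet. The main model without a block does so too, and its p for site and for the interaction would then tend to be too large. The values with slide as a block are given beside the infection results for the lists called and for the genes named apart from a list whose difference is given. The sites are balanced within slides.

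The numbers in the titles were checked for pairing. Deviations from the group mean correlated across probes between the 2 sites of one condition for equal numbers, at r from 0.219 to 0.597 over 6 pairs, and all 12 arrays had their best match at the other site under their own number. Each of these pairs also shared a slide. Samples of unequal number on one slide gave r from -0.40 to 0.09 between the 2 sites of one condition. Infected replicate 1 and control replicate 3 had no such comparison, so a shared slide cannot be told apart from a shared piglet for them. The numbers thus seem to pair the samples between the sites, a hint from the data and not from the labels. Infected and control samples of equal number gave r from -0.14 to 0.43 and are not paired.

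The procedure was tested on simulated data made from the 31845 probes, in 5 draws with 200 changed probes each. A 4-fold change was recovered for 76.4% of these probes in the comparison of infection at the inductive site, 78% at the effector site and 55.6% in the difference between sites, and a 2-fold change for 29.6%, 30.2% and 8.4%. The noise was drawn independently for each probe and array, without a slide effect or correlation between sites or genes. These shares are therefore not the power of the real design, in which infection and slide largely coincide. Alternatives changed the background correction, the normalization, the filter, the arrays in the model, the blocks, array weights, the variance model, the threshold, the probe that represents a gene and the test of the lists, and left out each array in turn. A fixed block for the possible animal in the comparisons of sites was added after seeing the data. Some genes are not reported here.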

Results

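The arrays measured transcript levels in the ileum of male piglets, 35 days old, either infected with PCV2, a small circular single-stranded DNA virus of pigs, or left uninfected. Tissue was taken 21 days after infection at the site where intestinal immune responses are started (inductive site, Peyer's patches and mesenteric lymph nodes) and at the site where they act (effector site, epithelium and lamina propria). The labels do not state whether each sample holds both tissues of its site. Each of the 4 groups had 3 arrays, and n = 3 per group holds for all differences below, which are on the log2 scale. At the effector site the 75th percentile of the signal was 396.1 to 454.3 units on infected and 288.6 to 339.1 units on control arrays, and at the inductive site 363.6 to 438.4 and 335.4 to 407.2. Log2 signals of arrays of one group correlated across probes at r from 0.960 to 0.983. The first principal component, with 44.6% of the variance, separated the 2 sites. On the second, with 15.0%, the arrays of the third slide, all infected, lay at 29.8 to 59.2. All other arrays lay at 1.80 or lower, and infected replicate 1, on the second slide, lay at -15.0 and -14.5.

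The first question was what distinguishes infected from control piglets at the inductive site. Probe A_72_P231032, which carries no gene symbol and the transcript cluster name TC614628, lay above background on all 3 infected and on 0 of 3 control arrays and was at least 5.41-fold higher in infected piglets (SE 0.22 log2, adjusted p = 3.91e-05). On the slide that holds both conditions it was at least 5.4-fold higher. A second probe without a symbol, A_72_P253527 (TC626656), passed at the margin (adjusted p = 0.0498) and lay above background on 2 of 3 infected and 0 of 3 control arrays, so that no fold is given. These were the only probes past the threshold, with 2 higher and 0 lower, and limma called 0 of 5892 named genes. At an unadjusted p under 0.05, 1272 probes were higher and 605 lower, where chance gives 1592 in all. Of the 9 other ways to part these 6 arrays 3 against 3, 2 gave more than these 1877 probes (2067 and 2516).

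Among named genes that did not pass, CD209, a lectin of macrophages and dendritic cells that binds pathogens, had the smallest p, with a difference of -2.09 (SE 0.40, adjusted p = 0.5255) and -1.68 on the shared slide. KRT18, a keratin of simple epithelia, differed by -1.2 (SE 0.27, adjusted p = 0.773). CPT1A, which imports fatty acids into mitochondria, differed by -0.57 (SE 0.15) and ANGPTL4, an inhibitor of lipoprotein lipase, by -1.11 (SE 0.31). FAM45A (-0.51), NT5DC1 (-1.34), PPIP5K1 (-0.69) and GPR1 (-1.05) also had small p in this direction. In the other direction stood CDH15, a cadherin (2.06, SE 0.51), NRDC (0.55), AGK (0.63), FITM1 (1.06) and the casein gene CSN1S2 (0.99). With slide as a block the values were -1.74 for CD209, -1.34 for KRT18, -0.57 for CPT1A, -1.51 for ANGPTL4, -0.42 for FAM45A, -1.38 for NT5DC1, -0.70 for PPIP5K1 and -1.49 for GPR1. In the other direction they were 0.91 for CDH15 (0.21 on the shared slide), 0.52 for NRDC, 0.46 for AGK, 0.69 for FITM1 and 0.44 for CSN1S2. SPTB and SLC17A4 belonged to the same set but lay above background on 1 of 6 arrays, so that no fold is given. The adjusted p of these genes lay between 0.5255 and 0.784. Of the fixed set, PIGR, the receptor that carries IgA across the epithelium, differed by -3.02 (SE 1.16, adjusted p = 0.826). The cytokine IL1B differed by 1.24 (SE 0.50), IFNG by 0.46 (SE 0.24) and TNF by 0.33 (SE 0.29). Interferon-induced ISG15 differed by 0.63 (SE 0.64), CXCL10 by 0.52 (SE 0.61), MX1 by 0.22 (SE 0.49) and IL10 by 0.18 (SE 0.32). MS4A1 (-0.21), CD3E (0.11), CD163 (-0.58), TJP1 (0.10), OCLN (-0.12) and MUC2 (0.03) lay within 1 standard error of 0, but not all did so within slides. On the shared slide and with the block, CD163 was 1.57 and 1.31, MS4A1 0.82 and 0.80, MUC2 -1.25 and -0.59, OCLN -0.48 and 0.13, CD3E 0.08 and -0.18 and TJP1 0.38 and 0.30. PIGR was -1.84 and -0.89, IL1B 2.53 and 2.24, CXCL10 1.21 and 0.93, TNF 0.66 and 0.66, IFNG 0.51 and 0.45, IL10 0.56 and 0.34, ISG15 -0.14 and 0.0077 and MX1 -0.0090 and 0.11. None of these genes passed with the block.

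**Figure D1:**
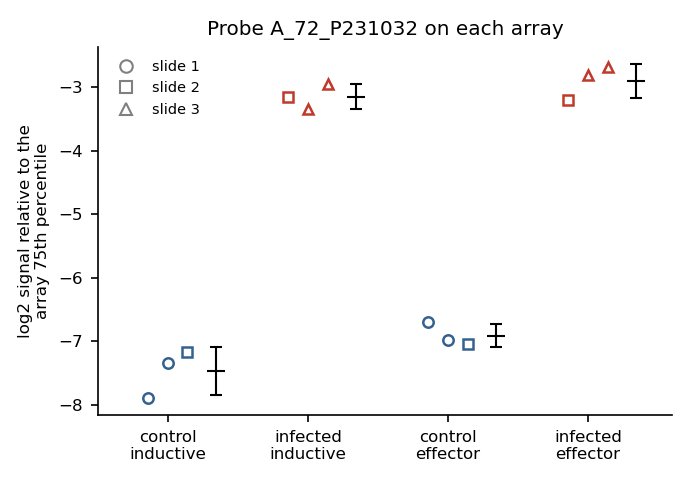
Log2 signal of probe A_72_P231032 relative to the 75th percentile of its array (y axis) in the 4 groups (x axis). Symbols are single arrays with their shape giving the slide, red for infected and blue for control, and the bar is the mean ± SD of 3 arrays. The infected means are -3.15 and -2.90 and the control means -7.48 and -6.91, where the probe was not above background.

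At the inductive site camera called 5 lists higher and 3 lower in infected piglets. Of 17 macrophage and monocyte genes 16 had negative differences, with a median of -0.61 (adjusted p = 9.27e-05, adjusted p = 0.846 with an estimated correlation), among them the scavenging receptors VSIG4 (-1.07, SE 0.34) and SIGLEC1 (-0.94, SE 0.36). The list had a median of 0.20 on the shared slide and of -0.04 with slide as a block. Of 16 cell junction genes 14 were negative, with a median of -0.68 (adjusted p = 0.00136, adjusted p = 0.846 with an estimated correlation), including the claudins CLDN3 (-1.55, SE 0.73) and CLDN7 (-1.56, SE 0.85). Its medians were -0.49 on the shared slide and -0.0014 with the block. Goblet cell and mucus genes had a median of -0.59 with 8 of 11 negative (adjusted p = 0.0113, adjusted p = 0.846 with an estimated correlation), including the secreted CLCA1 (-1.21, SE 0.48), and medians of -1.69 on the shared slide and -0.73 with the block.

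Of the lists called higher, smooth muscle genes had a median of 0.74 with 11 of 12 positive (adjusted p = 1.53e-04, adjusted p = 0.846 with an estimated correlation), for example desmin, DES (1.19, SE 0.52), and calponin, CNN1 (1.25, SE 0.61). On the shared slide the median was -0.10 and with the block -0.11. Fibroblast and matrix genes had a median of 0.23 (15 of 19 positive, adjusted p = 0.04, adjusted p = 0.846 with an estimated correlation). The median was -0.34 on the shared slide and -0.41 with the block. Immediate-early and heat shock genes had a median of 0.24 (13 of 16 positive, adjusted p = 0.00644, adjusted p = 0.846 with an estimated correlation), with the chaperone HSPH1 at 0.84 (SE 0.23). The median was 0.54 on the shared slide and 0.42 with the block. T helper and checkpoint genes had a median of 0.33 (10 of 14 positive, adjusted p = 0.0158, adjusted p = 0.846 with an estimated correlation), with CTLA4, a brake on T cell activation, at 0.67 (SE 0.27). The median was 0.53 on the shared slide and 0.51 with the block. T cell genes had a median of 0.15 (14 of 16 positive, adjusted p = 0.034, adjusted p = 0.846 with an estimated correlation). The median was 0.43 on the shared slide and 0.11 with the block. No list member passed, with 0 genes called over all genes tested and 0 adjusted over the list alone. Fry called 0 lists (smallest adjusted p = 0.898). The goblet cell list was the only one of the 8 still called with slide as a block (adjusted p = 5.85e-05). The p with the block takes both sites of a piglet as separate samples. It rests mainly on a single infected piglet against a single control piglet, so this call does not show that the difference holds apart from these piglets. Of 15 settings other than leaving out an array, the calls held in 13 for goblet cells, 12 for macrophages, junctions, smooth muscle and immediate-early genes, 11 for T helper, 10 for T cell and 9 for matrix genes. With the normexp correction the T helper median was 0.10 and not called, and the goblet cell median was -0.27 and the junction median -0.43.

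Without control replicate 3 of this site, 6 of the 8 lists no longer passed (adjusted p from 0.0785 to 0.389), those for smooth muscle and macrophages did, and 3 lists were called in all. Without control replicate 2, 13 lists were called. T cell genes also missed the threshold without control replicate 1 (adjusted p = 0.0782), infected replicate 1 (0.0904) or infected replicate 2 (0.278). Goblet genes did so without infected replicate 1 (0.274). Fibroblast genes did so without control replicate 1 (0.551), infected replicate 2 (0.873) or control effector replicate 3 (0.0539). T helper and immediate-early genes did so without infected replicate 3 (0.0771 and 0.061).

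At the effector site the same question gave 1 probe. A_72_P231032 was again above background on all 3 infected and 0 of 3 control arrays and was at least 5.02-fold higher (SE 0.22 log2, adjusted p = 8.46e-05), and at least 3.54-fold higher on the shared slide. Limma called 0 named genes. At an unadjusted p under 0.05 2076 probes were higher and 1348 lower, where chance gives 1592. Of the 9 other ways to part these 6 arrays, 3 gave more than these 3424 probes (4116, 4287 and 4525). The named genes with the smallest p included CSN1S2 (at least 1.42-fold higher) and KLF1, a transcription factor of red cell precursors (at least 1.22-fold higher), each above background on 3 of 3 infected and 0 of 3 control arrays (adjusted p = 0.204). CLSTN3 differed by 0.97 (SE 0.16, adjusted p = 0.204). FADS2, a fatty acid desaturase, differed by 1.37 (SE 0.24, adjusted p = 0.239), and with slide as a block it passed (1.93, adjusted p = 0.0333). The p with the block takes the 2 sites of a piglet as separate samples and rests mainly on 1 piglet against 1. AWN, a spermadhesin, differed by 2.18 (SE 0.41), and it and FADS2 lay above background on 1 of 3 control arrays. RNASE12, SERTM1 and AACS lay above background on 2, 1 and 2 infected and 0 control arrays, and no fold is given. CPT1A differed by -0.81 (SE 0.15, adjusted p = 0.263). The ribonuclease ANG differed by -0.71, KRT4 by -0.70, SSR1 of the translocon by -0.62, the ribosomal RPL11 by -0.48, the neurokinin precursor TAC3 by -2.08 (SE 0.52) and VARS2 by -0.51. C4H1orf189 lay below background in both groups. Of the fixed set, IL1B differed by 1.59 (SE 0.50, adjusted p = 0.404) and PIGR by -2.48 (SE 1.16). The values of the others were ISG15 0.76 (SE 0.64), CXCL10 0.69 (SE 0.61), IFNG 0.36 (SE 0.24) and TNF 0.29 (SE 0.29). None of MX1 (0.08), IL10 (0.04), MS4A1 (0.84, SE 0.55), CD163 (0.44), CD3E (0.24), TJP1 (0.14), OCLN (-0.45) and MUC2 (0.03) passed. On the shared slide and with the block, PIGR was 0.60 and -0.35, IL1B 2.30 and 2.59, CD163 2.08 and 2.33, MUC2 0.07 and -0.59, OCLN 0.41 and -0.20 and CD3E -0.31 and -0.05. ISG15 was 0.28 and 0.13, CXCL10 0.82 and 1.10, IFNG 0.29 and 0.34, TNF 0.61 and 0.61, MX1 0.09 and -0.03, IL10 -0.0061 and 0.21 and TJP1 0.26 and 0.34. MS4A1 was 1.84 with the block and not above background on the control array of the shared slide. With the block CLSTN3 was 0.84, AWN 1.40, CPT1A -0.81, ANG -0.51, KRT4 -0.63, SSR1 -0.67, RPL11 -0.41, TAC3 -1.77 and VARS2 -0.55.

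Camera called 8 lists higher and 6 lower at the effector site. All 12 smooth muscle genes were positive, with a median of 0.87 (adjusted p = 3.7e-04, adjusted p = 0.674 with an estimated correlation). The median was -0.01 on the shared slide and -0.03 with slide as a block. Fibroblast and matrix genes followed (median 0.48, 18 of 19 positive, adjusted p = 0.0015, adjusted p = 0.674 with an estimated correlation), with fibronectin, FN1, at 0.96 (SE 0.26). The median was -0.19 on the shared slide and -0.12 with the block. Endothelial and lymph node stroma genes had a median of 0.39 (16 of 17 positive, adjusted p = 0.00906, adjusted p = 0.674 with an estimated correlation). The median was 0.21 on the shared slide and 0.39 with the block. Enteric neuron and glia genes had a median of 0.51 (9 of 9 positive, adjusted p = 0.0194, adjusted p = 0.674 with an estimated correlation). The median was 0.08 on the shared slide and 0.02 with the block. Cytokine and chemokine genes had a median of 0.40 (36 of 45 positive, adjusted p = 0.00199, adjusted p = 0.674 with an estimated correlation), with the chemokine CCL3L1 at 0.72 (SE 0.21) and IL1A at 1.16 (SE 0.36). The median was 0.34 on the shared slide and 0.54 with the block. Cytotoxic lymphocyte genes had a median of 0.40 (15 of 20 positive, adjusted p = 0.0172, adjusted p = 0.674 with an estimated correlation), with CD8A at 0.82 (SE 0.31) and CD8B at 0.88 (SE 0.32). The median was 0.32 on the shared slide and 0.30 with the block. Immediate-early and heat shock genes had a median of 0.22 (12 of 16 positive, adjusted p = 0.0242, adjusted p = 0.674 with an estimated correlation). The median was 0.25 on the shared slide and 0.29 with the block. Erythroid genes had a median of 0.52 (5 of 6 positive, adjusted p = 0.0299, adjusted p = 0.674 with an estimated correlation). The median was 0.27 with KLF1 and HBE1 at their bounds, 0.32 on the shared slide and 0.24 with the block. The sign turned to -0.10 with the normexp background correction, under which the median of all probes moved to -0.14 and 6 lists were called in all.

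Of the lists called lower, cell cycle genes had a median of -0.44 with 20 of 22 negative (adjusted p = 0.00166, adjusted p = 0.674 with an estimated correlation), for example the mitotic CDC20 (-0.93, SE 0.43) and E2F1 (-0.66, SE 0.29). On the shared slide this median was 0.72 and with the block 0.62 (adjusted p = 3.06e-05, in the other direction). Antigen presentation genes had a median of -0.29 (21 of 25 negative, adjusted p = 0.00199, adjusted p = 0.674 with an estimated correlation), with B2M, the light chain of class I molecules, at -0.52 (SE 0.16). The median was 0.25 on the shared slide and 0.13 with the block. Plasma cell and IgA genes had a median of -0.74 (9 of 10 negative, adjusted p = 0.0162, adjusted p = 0.674 with an estimated correlation), with the B cell survival factor TNFSF13B at -1.52 (SE 0.70). The median was -0.21 on the shared slide and -0.27 with the block. Goblet cell genes had a median of -0.41 (9 of 11 negative, adjusted p = 0.0162, adjusted p = 0.674 with an estimated correlation). The median was -0.64 on the shared slide and -1.03 with the block. Cell junction genes had a median of -0.65 (14 of 16 negative, adjusted p = 0.0122, adjusted p = 0.674 with an estimated correlation). The median was 0.49 on the shared slide and 0.08 with the block. Genes of the unfolded protein response had a median of -0.34 (10 of 13 negative, adjusted p = 0.0394, adjusted p = 0.674 with an estimated correlation). The median was -0.03 on the shared slide and -0.11 with the block. With slide as a block, 2 of the 14 lists were called in the direction given, goblet cells (adjusted p = 9.39e-06) and cytokines (adjusted p = 0.0443). These p again take the 2 sites of a piglet as separate samples and rest mainly on 1 piglet against 1. Of 15 settings other than leaving out an array, the calls held in 13 for cytokines, 12 for cytotoxic, immediate-early, smooth muscle, matrix and endothelial genes and 11 for cell cycle, plasma cell, junction and antigen presentation genes. With normexp the cytokine median was 0.17 and the cytotoxic median 0.20, and the antigen presentation median was -0.15 with quantile normalization or the series matrix. Goblet cell genes kept it in 9 and missed it also with normexp, quantile normalization, the series matrix and the stricter filter. Enteric neuron genes kept it in 8, with a median of 0.03 under normexp, and missed it also with no filter, the stricter filter and array weights. Erythroid genes kept it in 7 of 14. Genes of the unfolded protein response kept it in 6, with medians from -0.53 to -0.0087 over all settings, and missed it also with normexp, quantile normalization, the series matrix, no filter, the stricter filter and only the 2 groups in the model.

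No member of these 31 lists passed over all genes tested. Adjusted over the list alone, KLF1 (erythroid), CD207 of Langerhans-type dendritic cells (1.61, SE 0.43), the desaturase SCD (1.10, SE 0.27), GPD1 of glycerol metabolism (0.68, SE 0.18) and, in the other direction, CPT1A passed, and fry called 0 lists (smallest adjusted p = 0.409). With slide as a block SCD passed over all genes tested (1.84, adjusted p = 0.0269), with the same limit of the block, mainly 1 piglet against 1. Each of the 14 lists missed the threshold without at least 1 array. Leaving out control replicate 1 ended 8 calls (adjusted p from 0.0678 to 0.68, with 8 lists called in all). Control replicate 2 ended 7 (0.0539 to 0.938) and control replicate 3 ended 4 (0.0509 to 0.0692). Infected replicates 1, 2 and 3 ended 3 (0.076 to 0.175), 5 (0.122 to 0.4, with 9 lists called in all) and 6 (0.0619 to 0.569). Control inductive replicate 3 ended 1 (0.0541).

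**Figure D2:**
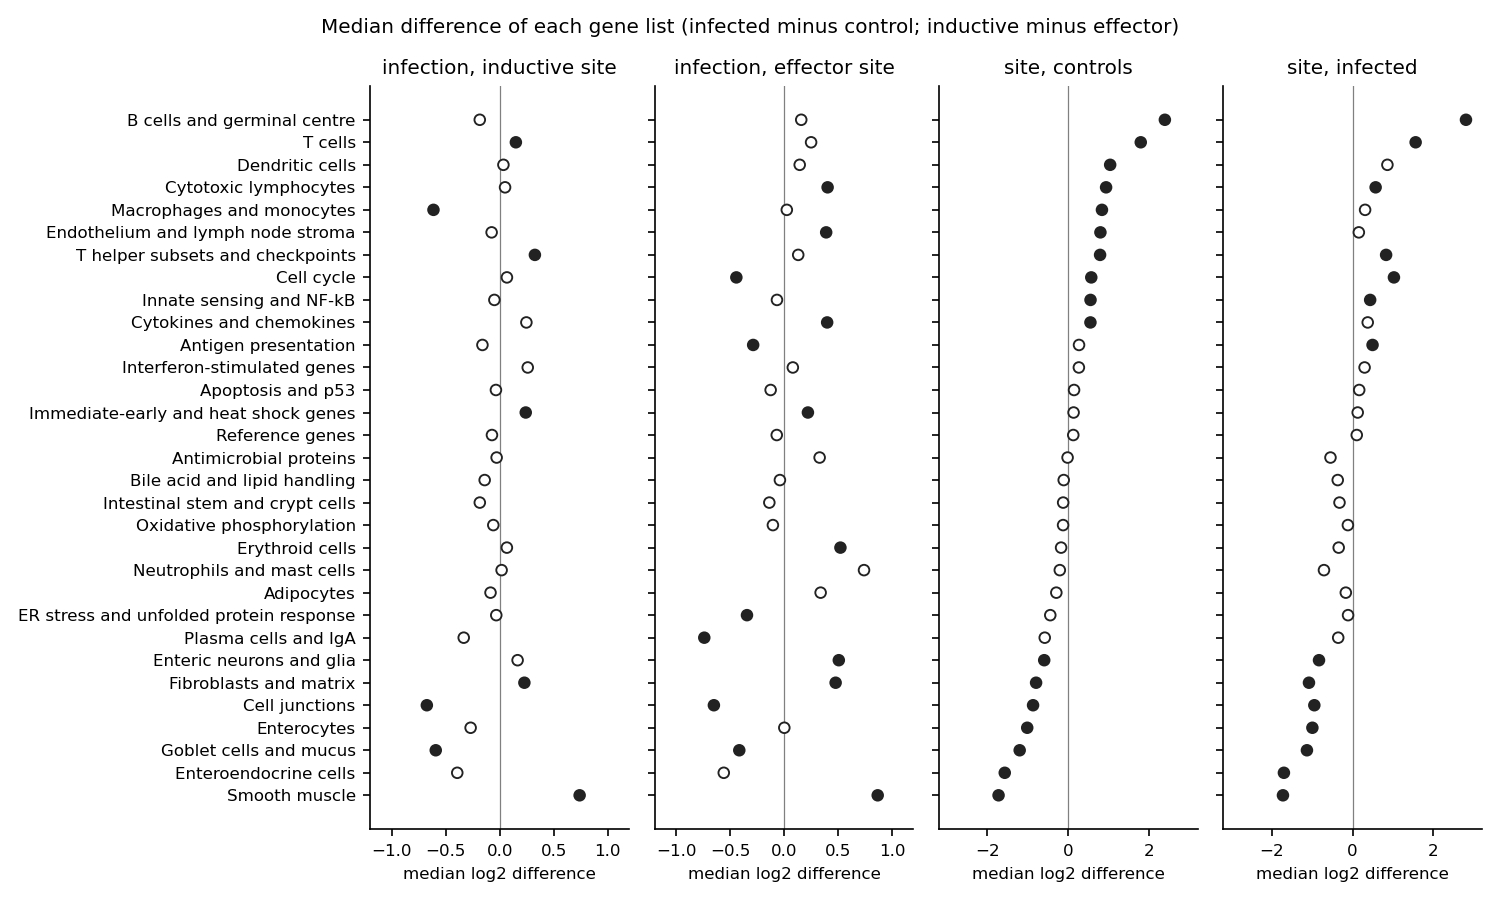
Median log2 difference (x axis) of each of the 31 gene lists (y axis), infected minus control in the 2 left panels and inductive minus effector in the 2 right panels, with filled symbols where camera at the preset correlation gave an adjusted p under 0.05 and open symbols elsewhere. The medians reach 0.87 in size for infection and 2.80 for site, and the x axes of the left and right panels differ in range.

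Whether infection acted differently at the 2 sites was tested by the interaction. The model takes the 2 sites of a piglet as separate samples. If equal numbers are one piglet, its p here tends to be too large. A low count of probes therefore does not show that the infection difference was equal at the 2 sites. Limma called 0 probes (smallest adjusted p = 1), and at an unadjusted p under 0.05 the infection difference was higher at the effector site for 262 probes and lower for 187, against 1592 in all by chance. CD209 (3.15, SE 0.56), the growth factor carrier IGFBP3 (2.35, SE 0.67), FADS2 (1.22, SE 0.34, above background on 1 of 3 control effector arrays) and the fatty acid elongase ELOVL5 (0.97, SE 0.27) had small p among genes with positive values. TAC3 (-1.92, SE 0.73), SEC22C (-0.87), SEC31B (-0.80), MPZL3 (-0.66) and MLLT1 (-0.62) had small p among those with negative values. SERTM1, AACS, RNASE12, GAB1 and LY6G6F had small p too but lay above background on 0 arrays of at least 1 group, so that no difference is given. Of the fixed set MS4A1 (1.04, SE 0.78), CD163 (1.02, SE 1.03), PIGR (0.54, SE 1.64), IL1B (0.35, SE 0.71), OCLN (-0.33), CXCL10 (0.17), ISG15 (0.13), CD3E (0.13), MX1 (-0.14), IL10 (-0.14), IFNG (-0.11), TNF (-0.04), TJP1 (0.04) and MUC2 (-0.01) did not pass either. On the shared slide PIGR was 2.44, MUC2 1.32 and OCLN 0.89, and the signs of MUC2, OCLN, IL1B (-0.23), CXCL10 (-0.39), CD3E (-0.38), MX1 (0.10) and TJP1 (-0.12) turned there.

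Camera called 3 lists in the interaction. All 22 cell cycle genes had a lower infection difference at the effector site, with a median of -0.46 (adjusted p = 9.79e-06, adjusted p = 0.922 with an estimated correlation), for example the mitotic motor KIF11 (-0.74, SE 0.45). Of 17 endothelial and lymph node stroma genes 16 were positive, with a median of 0.55 (adjusted p = 2.69e-04, adjusted p = 0.922 with an estimated correlation), for example CLDN5 of vessel walls (0.94, SE 0.56) and PECAM1 (0.67, SE 0.39). Of 17 macrophage genes 15 were positive, with a median of 0.57 (adjusted p = 0.00148, adjusted p = 0.922 with an estimated correlation), for example the mannose receptor MRC1 (0.99, SE 0.48). The medians were 0.02, 0.17 and -0.09 on the slide that holds both conditions, and the block leaves them unchanged because the sites are balanced within slides. The macrophage list missed the threshold without control effector replicate 1 (adjusted p = 0.204), infected effector replicate 1 (0.131) or infected inductive replicate 3 (0.0687). The endothelial list did so without control effector replicate 1 (0.323). With the replicate number as a block, which also sets infected and control samples of equal number together although they are not paired, 9 lists were called, and without single arrays 4 to 10. No list member passed, over all genes or adjusted over the list alone, and fry called 0 lists (smallest adjusted p = 0.971).

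**Figure D3:**
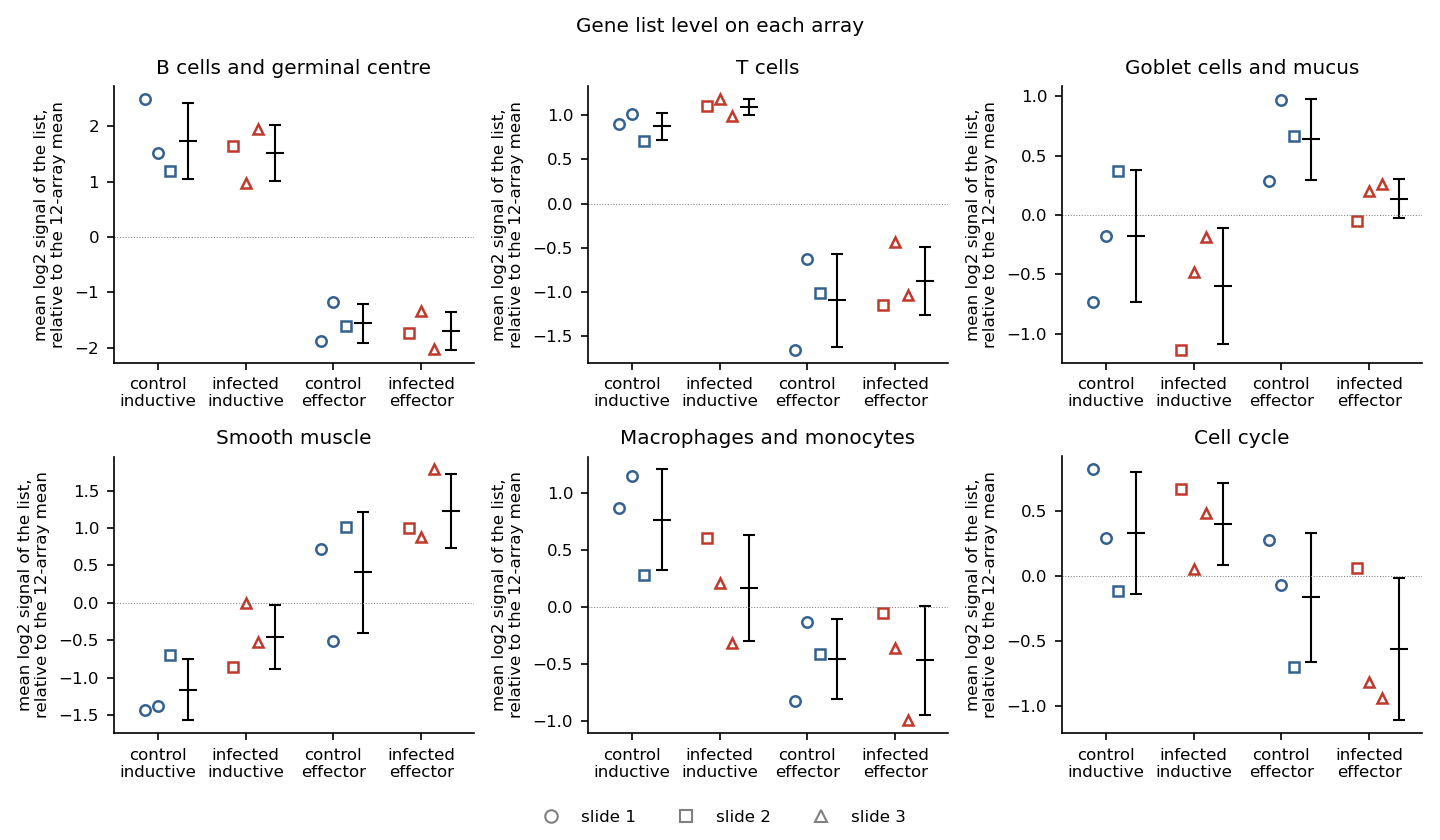
Mean log2 signal of the measured genes of 6 lists on each array, relative to the mean over the 12 arrays (y axis), by group (x axis). Symbols are single arrays with their shape giving the slide, red for infected and blue for control, and bars are mean ± SD of 3 arrays. In the B cell panel the means are 1.74 and 1.52 at the inductive and -1.56 and -1.70 at the effector site, control and infected.

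The comparison of sites in control piglets shows what each site holds. Limma called 2293 probes higher and 1671 lower at the inductive site (481 and 318 named genes), and with the possible animal as a random block 8040 probes in all. TNFSF11, the cytokine RANKL, was at least 27.3-fold higher (adjusted p = 2.64e-06), ZP3 at least 12-fold (adjusted p = 6.69e-04) and LY6G6F at least 7.81-fold, each above background on 3 inductive and 0 effector arrays. The B cell genes MS4A1 (CD20, 6.62, SE 0.55, adjusted p = 2.09e-04, above background on 2 of 3 effector arrays), ELL3 (6.39, SE 0.47) and VPREB3 (5.87, SE 0.49) were higher too, as was CD5L of macrophages (5.01, SE 1.21, adjusted p = 0.0258). Lower at the inductive site were CHRM2, the muscarinic receptor of smooth muscle (at least 4.56-fold), and RESP18 of endocrine cells (at least 4.1-fold). So were C1QTNF3 (-2.84, SE 0.64), HAND2, a transcription factor of enteric neurons (-2.68, SE 0.49), VSTM2L (-2.57, SE 0.51), CDH19 (-2.52, SE 0.45), and the carbonic anhydrase CA4 (-2.49, SE 0.67, adjusted p = 0.0365). VSTM2L and CDH19 lay above background on 2 and 1 of 3 inductive arrays.

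Of the fixed set, CD3E (1.60, SE 0.30, adjusted p = 0.0111) and TNF (1.14, SE 0.29, adjusted p = 0.0314) were higher at the inductive site of controls and MUC2, the main secreted mucin, was lower (-1.79, SE 0.47, adjusted p = 0.0344). CD163 (1.63, SE 0.73), IL10 (0.83, SE 0.32), CXCL10 (0.55, SE 0.61), ISG15 (0.42, SE 0.64), MX1 (0.37, SE 0.49), IFNG (0.27, SE 0.24), IL1B (0.18, SE 0.50), PIGR (-1.37, SE 1.16), OCLN (-0.85, SE 0.41) and TJP1 (-0.40, SE 0.25) did not pass. Some calls depended on single arrays. Without at least one of control inductive replicates 1 to 3 or effector replicates 1 to 3, CA4, MUC2, CD5L, C1QTNF3, TNF, CHRM2, RESP18 and VSTM2L missed the threshold, at adjusted p between 0.0501 and 0.135. CA4 did so without infected inductive replicate 1 (0.0511) and without a filter on dim probes (0.0514). With only the control arrays in the model, CA4 (adjusted p = 0.0962), MUC2 (0.0784) and CHRM2 (0.0545) missed it, as did MUC2 with the normexp correction (0.07) and TNF with the possible animal as a fixed block (0.0607). With only these 6 arrays in the model 1380 probes were called. The count was 1084 without control inductive replicate 1, 1346 without control inductive replicate 2, 1928 without control effector replicate 3 and 2360 without control effector replicate 1.

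By list, 15 of 15 B cell and germinal centre genes had positive differences between the sites of controls, with a median of 2.39, or 2.14 with FCER2 at its bound. Of these, 14 were called and 15 adjusted over the list alone (adjusted p = 2.59e-12, adjusted p = 0.485 with an estimated correlation). Of 16 T cell genes 14 were called and 15 adjusted over the list alone, with a median of 1.79, or 1.68 with BCL11B and CD28 at their bounds (adjusted p = 7.42e-12, adjusted p = 0.485 with an estimated correlation), led by the homing receptor CCR7 (5.0, SE 0.33) and LEF1 (3.13, SE 0.34). Cytotoxic (0.93, adjusted p = 4.54e-04), T helper (0.79, adjusted p = 0.0471), macrophage (0.83, adjusted p = 0.00147), dendritic (1.04, adjusted p = 0.0316), innate sensing (0.55, adjusted p = 0.00118) and cytokine lists (0.55, adjusted p = 0.00233) also had higher medians, each with adjusted p = 0.485 with an estimated correlation. Members were CD8B (2.18, SE 0.32), CTLA4 (1.63, SE 0.27), the chemokine CCL20 (4.51, SE 0.49), IL18 (2.96, SE 0.25), TLR2 (2.26, SE 0.34) and SIGLEC1 of lymph node macrophages (at least 6.06-fold). With members at their bounds the T helper median was 0.63, the innate sensing median 0.52 and the cytokine median 0.49. The endothelial and stroma list (0.79, adjusted p = 0.00711, adjusted p = 0.574 with an estimated correlation) held clusterin, CLU (2.96, SE 0.44), and the lymph node chemokine CCL21 (2.84, SE 0.60). Cell cycle genes had a median of 0.57 (adjusted p = 0.0353, adjusted p = 0.723 with an estimated correlation).

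Lists that camera called lower at the inductive site of controls were those of the epithelium and the gut wall. Smooth muscle genes had a median of -1.72 (6 of 12 called, 12 adjusted over the list alone, adjusted p = 2.48e-06, adjusted p = 0.485 with an estimated correlation), with smoothelin, SMTN, at -2.14 (SE 0.52) and MYOCD at -2.06 (SE 0.47). Matrix (-0.79, adjusted p = 4.66e-04), enteric neuron (-0.59, adjusted p = 0.0149), goblet cell (-1.2, adjusted p = 0.00756) and enteroendocrine genes (-1.57, adjusted p = 0.00656) were lower too, each with adjusted p = 0.485 with an estimated correlation. Examples were UCHL1 (-1.79, SE 0.38), CLCA1 (-1.70, SE 0.48) and somatostatin, SST (-1.82, SE 0.48). THY1 of the matrix list was higher (1.97, SE 0.29). Enterocyte genes had a median of -1.01 with 22 of 26 negative (adjusted p = 0.0112, adjusted p = 0.723 with an estimated correlation). Junction genes had a median of -0.87 (adjusted p = 0.00366, adjusted p = 0.627 with an estimated correlation). Of both lists 0 members were called. Within slides, the B cell median was 2.70 and 2.37, the smooth muscle median -1.58 and -1.94 and the enterocyte median -1.54 and 0.04. The junction (-1.29 and -0.10), macrophage (1.18 and 0.21), enteroendocrine (-1.98 and -0.58), cytokine (0.81 and 0.27) and endothelial medians (0.96 and 0.33) were also smaller on the second slide. The matrix (-0.78 and -1.01) and cell cycle medians (0.53 and 0.58) were not. Fry called 9 of the 31 lists. Of the lower lists it called smooth muscle and missed the matrix, enteric neuron, goblet cell, enteroendocrine, enterocyte and junction lists. Of the lists that camera called higher it missed the endothelial and cell cycle lists. Without control effector replicate 1 the T helper, enterocyte, junction, dendritic and endothelial lists missed the threshold (adjusted p from 0.0722 to 0.474), and without effector replicate 3 the T helper, cell cycle and neuron lists (0.0511 to 0.341). Over all other settings and arrays left out, the enterocyte median ran from -1.70 to -0.21 and the junction median from -1.14 to -0.45. Without inductive replicate 1 the T helper and cell cycle lists missed it (0.0745 and 0.312), without inductive replicate 2 the enterocyte and dendritic lists (0.0529 and 0.0514) and without inductive replicate 3 the T helper list (0.0541). The T helper list was called under 6 of 16 other settings. The dendritic list was called under 12 of 15 and missed the threshold with the possible animal as a fixed block, the replicate block and an estimated correlation, and the T helper list missed it under these too.

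In infected piglets limma called 3328 probes higher and 2985 lower at the inductive site (624 and 593 named genes), and 10953 in all with the possible animal as a random block. TNFSF11 was at least 21.9-fold, LY6G6F at least 14.8-fold and ZP3 at least 13.4-fold higher. Also higher were ELL3 (5.88, SE 0.47), MS4A1 (5.58, SE 0.55), VPREB3 (5.27, SE 0.49) and CCR7 (4.94, SE 0.33). Lower were the gut peptides CALCB (-3.22, SE 0.90, adjusted p = 0.0324) and PYY (-2.77, SE 0.73, adjusted p = 0.0262) and the goblet cell product RETNLB (-3.0, SE 0.81, adjusted p = 0.0288). So were HAPLN1 (-3.02, SE 0.65), the potassium channel KCNG1 (-2.74, SE 0.50), RXRG (-2.68, SE 0.51) and LRRTM3 (at least 2.02-fold). The probe for the serotonin receptor HTR2A lay above background on 3 effector and 0 inductive arrays. LRRTM3 (-0.29, adjusted p = 0.132) and MUC2 (adjusted p = 0.0703) missed the threshold with the normexp correction, and CALCB (adjusted p = 0.0665) and TNF (0.0518) with only the infected arrays in the model. Of the fixed set CD3E (1.47, SE 0.30, adjusted p = 0.0123), TNF (1.18, SE 0.29, adjusted p = 0.0212) and MUC2 (-1.78, SE 0.47, adjusted p = 0.0266) passed. IL10 (0.97), CD163 (0.61), MX1 (0.52), IFNG (0.38), CXCL10 (0.38), ISG15 (0.30), IL1B (-0.17), TJP1 (-0.44), OCLN (-0.52) and PIGR (-1.91) did not. TNFRSF1B had another probe called in the opposite direction. CALCB, PYY, RETNLB, HAPLN1, MUC2, TNF and CD3E missed the threshold without one of infected inductive replicates 1 and 3 or effector replicates 1, 2 and 3, at adjusted p up to 0.115. The count of probes was 1536 without infected effector replicate 3, 1731 without infected inductive replicate 3 and 1925 without infected inductive replicate 1.

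By list in infected piglets, all 15 B cell genes were called (median 2.80, or 2.52 with FCER2 at its bound, adjusted p = 3.33e-11, adjusted p = 0.587 with an estimated correlation) and 15 of 16 T cell genes (median 1.56, or 1.47 with bounds, adjusted p = 7.34e-11, adjusted p = 0.587 with an estimated correlation). The same 2 counts resulted adjusted over the list alone. Cell cycle genes were higher (1.02, 22 of 22 positive, 6 called, 15 adjusted over the list alone, adjusted p = 4.47e-05, adjusted p = 0.587 with an estimated correlation). So were the cytotoxic (0.57, adjusted p = 0.0105), T helper (0.83, adjusted p = 0.0132), innate sensing (0.44, adjusted p = 0.00477) and antigen presentation lists (0.50, 25 of 25 positive, adjusted p = 0.00647), all with adjusted p = 0.587 with an estimated correlation. Smooth muscle (-1.72, 11 of 12 called, 12 adjusted over the list alone, adjusted p = 2.42e-06, adjusted p = 0.587 with an estimated correlation) and matrix lists (-1.08, adjusted p = 3.69e-05, adjusted p = 0.587 with an estimated correlation) were lower. The enteric neuron (-0.83, adjusted p = 0.0057), enterocyte (-0.99, adjusted p = 0.00602), junction (-0.94, adjusted p = 0.00647), enteroendocrine (-1.70, adjusted p = 0.00777) and goblet cell lists (-1.13, adjusted p = 0.0333) were lower, again with adjusted p = 0.587 with an estimated correlation. Members were ACTA2 (-1.2, SE 0.22), UCHL1 (-2.01, SE 0.38), SCG2 (-2.55, SE 0.53) and CLCA1 (-2.50, SE 0.48). Macrophage (0.31), dendritic (0.86), cytokine (0.38) and endothelial lists (0.16) did not pass here (adjusted p = 0.177, 0.144, 0.0578 and 0.494). Within slides the B cell median was 2.65 and 2.88, the smooth muscle median -1.99 and -1.65 and the enterocyte median -1.12 and -1.18. Fry called 9 lists, not all of them called by camera. Of the lists that camera called, it missed cell cycle, cytotoxic, antigen presentation, enterocyte, junction, enteroendocrine and goblet cell genes. The junction list missed the threshold without effector replicate 1 (adjusted p = 0.0716) and the goblet list without effector replicate 2 (0.0621) or inductive replicate 1 (0.0785). The antigen presentation list did so without effector replicate 3 (0.165) and the cytotoxic list without inductive replicate 2 (0.0543).

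**Figure D4:**
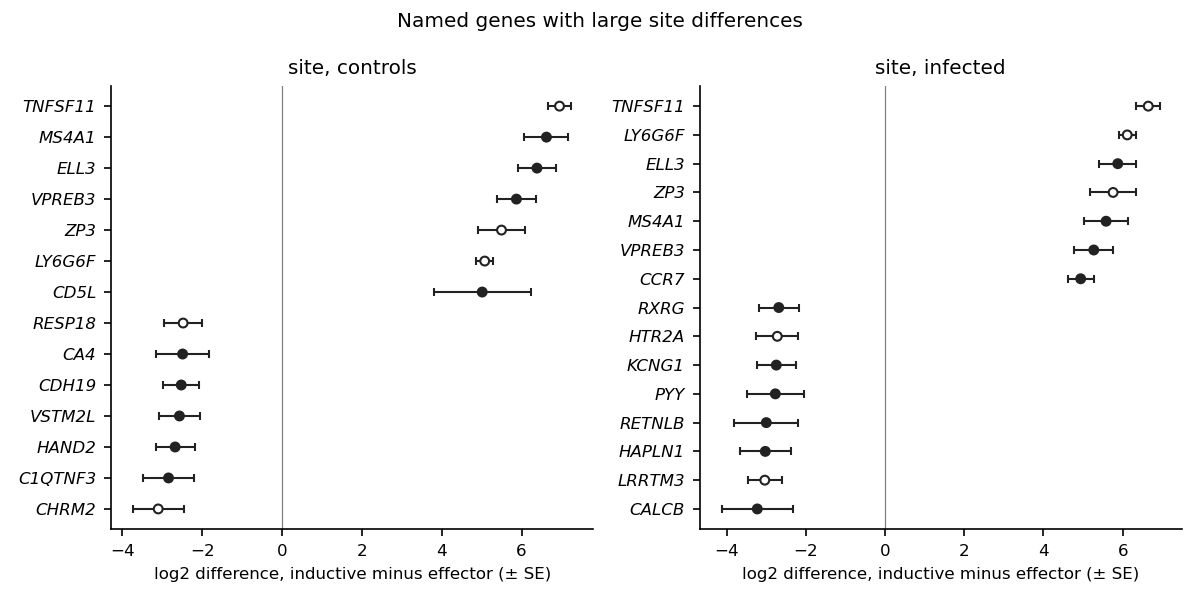
Log2 difference between the sites, inductive minus effector, with its standard error (x axis), for named genes with large differences (y axis) in control (left) and infected piglets (right). Open symbols mark genes whose probe was above background on 0 of 3 arrays of the lower group, for which the fitted difference is no measure of size. Among filled symbols MS4A1 is highest in controls and ELL3 in infected piglets.

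Across conditions, 369 named genes were called higher and 276 lower at the inductive site in both, where independent calls would give 50.9 and 32, and 0 genes were called in opposite directions. Both comparisons come from one fit with a shared spread per probe. Their calls are therefore not independent, and the excess over these counts is no test. Which site differences changed with infection is the interaction given above, in which 0 probes passed. The share of genes whose 3 arrays of one group all lay above or below the 3 of the other was 10.3% and 12.3% for infection at the inductive and the effector site and 32.5% and 45.9% for site in controls and in infected piglets, where chance gives 10%.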

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

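All tests of explanations in this part were chosen after the results were seen, except the regrouping of arrays. The prediction for differences between individual piglets is marked as written beforehand, but it concerns a probe that the results had already picked.

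The infection difference of 3 gene lists differed between the sites by the interaction test. Macrophage genes had a median interaction of 0.57 (-0.61 at the inductive and 0.03 at the effector site), cell cycle genes of -0.46 (0.07 and -0.44) and endothelial and lymph node stroma genes of 0.55 (-0.08 and 0.39), and each has adjusted p = 0.922 with an estimated correlation. Over all other settings and arrays left out, the macrophage interaction ran from 0.30 to 0.80 and the endothelial one from 0.22 to 0.71. The macrophage median at the effector site was -0.11 with quantile normalization or the series matrix.

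Cell cycle genes are the first pattern, with the interaction below 0 for 22 of 22 genes. The sign did not rest on a single array, since without each of the 12 arrays in turn the median stayed below 0. Camera also called the list each time, with a highest adjusted p of 0.0453. That p cannot argue against noise of the arrays. At the same preset correlation, each other grouping of the piglets gave 7 to 12 lists in the interaction. The size of the median of -0.46 did depend on single arrays. It was -0.20 without control inductive replicate 3, -0.26 without control effector replicate 1 or infected effector replicate 3, -0.74 without control inductive replicate 1, -0.81 without control effector replicate 3 and -0.82 without infected effector replicate 1. Fewer B cells at the effector site of infected piglets, which would carry dividing germinal centre cells with them, needs a B cell median of at most -0.23. The B cell median was 0.14, and its 15 members, of which 0 are in another list, spread by an SD of 0.65. That SD lies between genes and does not measure the spread between piglets, so this test cannot decide. Fewer B cells may still apply and cannot be told apart from other causes. A real difference of the infection response between the sites stays open and was not tested further, and on the slide that holds both conditions the median was 0.02.

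Smooth muscle genes had medians above 0 for infection at both sites (0.74 and 0.87), with adjusted p = 0.846 and 0.674 with an estimated correlation and 0 members called. The medians were -0.11 and -0.03 with slide as a block. A slide difference may apply, since on the slide that holds both conditions the higher of the 2 medians was -0.012. More muscle wall in the tissue pieces of infected piglets cannot be told apart from it. The lowest of the 4 medians of the enteric neuron and matrix lists was 0.17, but this value, of neurons at the inductive site, was -0.036 with the normexp correction, -0.17 on the shared slide and -0.12 with slide as a block, where the matrix medians were -0.41 and -0.12. With normexp the median of all probes at the inductive site moved less than that of the neuron genes, from 0.017 to -0.044. The smooth muscle and matrix medians there did not fall with it (0.77 and 0.27). The brightest muscle genes were abundant (DES 6.69 and 5.50 at the inductive site, 8.33 and 7.50 at the effector site, infected and control, log2 over the 75th percentile). Of the 12 smooth muscle, 19 matrix and 9 neuron genes 0 are in another list. An effect of infection on the muscle layer stays open, and the tests do not part these explanations.

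Probe A_72_P231032 is the last pattern, above background on every infected and 0 control arrays. A slide difference is argued against, because on the shared slide the infected array was higher than the background limit of the control array by at least 1.82 at each site, where 1 array against 1 has an SE of 0.38. A difference between individual piglets may apply: of the other ways to part the 6 piglets 3 against 3, the one that sets infected replicates 1 and 2 with control replicate 3 gave 10 probes that were on in 3 piglets, off in the other 3 and at least 4-fold apart in the signals as read, against 1 in the real grouping. Infection itself stays open as a biological explanation, and the target of the probe is not known from the sources used here.

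With 3 arrays against 3 there are 10 ways to part the arrays, too few for a share under 0.05. For infection at the inductive site the 2 probes were matched by 1 of the 10, the real one, and the highest other gave 1, while its 8 lists were matched or exceeded by 8 of 10, with up to 10 lists elsewhere. At the effector site 1 of 10 gave the 1 probe (highest other 0) and 4 of 10 gave 14 lists (up to 21). In the interaction 10 of 10 gave 0 probes and 10 of 10 gave 3 lists or more, up to 12. One grouping, infected replicate 1 with control replicates 1 and 2, keeps slides 1 and 3 apart as the real one does and exchanges only the 2 piglets of slide 2. It gave 10 lists at the inductive site, 9 at the effector site and 7 in the interaction, against 8, 14 and 3 in the real grouping under the same model. At an unadjusted p under 0.05 in limma it gave 2067 probes at the inductive and 4287 at the effector site. The real grouping gave fewer, 1877 and 3424. With slide as a block, which was not fitted to the other grouping, the real one gave 3, 4 and 4. For site in controls 1 of 10 gave 3964 probes (highest other 6, and 0 among those that also part every pair of numbers) and 1 of 10 gave 17 lists (highest other 15, and 14). For site in infected piglets 1 of 10 gave 6313 probes (highest other 1, and 0) and 5 of 10 gave 14 lists (highest other 17, and 17). The other groupings that part every pair set arrays of both sites together.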

How the results depend on the processing

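The possible animal as a fixed block was tried only after seeing the data, and all other settings were fixed before. Of the 152 counts of probes or lists under the settings other than leaving out an array, 108 stayed within 1.5 times the reported count. The other counts follow, with the reported value of 2 probes and 8 lists for infection at the inductive site, 1 and 14 at the effector site, 0 and 3 in the interaction, and 3964 and 6313 probes and 17 and 14 lists for site in controls and infected piglets. The cause was not tested unless given. The normexp correction gave 0 probes at both sites for infection, 6 lists at the effector site and 5 in the interaction. With only probes above background on all arrays, 0 probes were called at both sites, because the probes called are then left out. At the inductive site 1 probe was called with quantile normalization, no filter, the series matrix, slide as a random block, trended and robust variance, the possible animal as a random block or the replicate block. The replicate block also gave 2 probes at the effector site and 9 lists in the interaction, and this block, which also joins unpaired infected and control samples, moved no count for site by over 1.5 times (5754 and 8627 probes). It ended the calls of the T helper and dendritic lists for site in controls, as did the animal as a fixed block. The animal as a random block gave 8040 and 10953 probes for site, and as a fixed block 5731 and 8888. With only the 2 groups compared, 1380 probes were called for site in controls, from fewer arrays. Array weights gave 4 probes at the inductive site, 6137 for site in controls and 5 lists in the interaction. Adjusted p under 0.1 gave 3 probes at the effector site, and 6557 and 9662 for site. Adding a fold of 2 to the reported threshold gave 2598 and 3539 for site. Unadjusted p with a fold of 2 gave 491, 673 and 174 probes for infection at the inductive site, the effector site and the interaction. The mean of all probes of a gene gave 5 lists in the interaction. Camera with an estimated correlation called 0 lists in all 5 comparisons, and fry called 0 for infection at both sites and the interaction and 9 in each comparison of sites.

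Slide as a fixed block, whose infection difference averaged over the sites rests on 1 piglet against 1, gave 29 probes and 3 lists at the inductive and 34 probes and 4 lists at the effector site. Under it the lists for smooth muscle (-0.11) and fibroblasts (-0.41) at the inductive site and for cell cycle (0.62), smooth muscle (-0.027), fibroblasts (-0.12) and enteric neurons (0.025, tested as lower) at the effector site turned direction by the test. The medians of antigen presentation (0.13) and junction genes (0.075) at the effector site also rose above 0, still tested as lower. The erythroid list at the effector site turned with normexp (-0.10). Without infected inductive replicate 3 interferon-stimulated genes turned at the inductive site (-0.20) and in the interaction (0.34). Without control effector replicate 1 enterocytes turned at the effector site (0.66) and oxidative phosphorylation in the interaction (0.22). Over all arrays left out in turn these medians ran from -0.20 to 0.44, from -0.35 to 0.34, from -0.71 to 0.66 and from -0.17 to 0.22, and among genes past the threshold in either setting 0 turned direction. Named genes past it in neither changed sign in 23 values of other settings at the inductive site, 25 at the effector site, 46 in the interaction and 4 and 7 for site. Leaving out arrays in turn gave 1 to 3 probes and 3 to 13 lists at the inductive site, 1 to 4 and 8 to 15 at the effector site and 0 to 1 and 4 to 10 in the interaction. It gave 1084 to 4326 and 13 to 18 for site in controls and 1536 to 7331 and 13 to 18 for site in infected piglets. A group then has 2 arrays and is taken to vary like the others. Signal over background limits the calls of dim probes, such as A_72_P253527.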

Other observations

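The tests in this part were chosen after the results were seen, apart from the fixed gene lists.

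Among lists not described so far, interferon-stimulated genes had a median infection difference of 0.26 at the inductive site (21 of 27 positive, adjusted p = 0.0712) and 0.08 at the effector site (17 of 27, adjusted p = 0.708). Members with the smallest p included RSAD2 (0.68, SE 0.49, and 0.59, SE 0.49) and IFIT3 (0.62, SE 0.47) at the inductive site and OASL (0.90, SE 0.69) at the effector site. Neutrophil and mast cell genes had medians of 0.02 and 0.74 (adjusted p = 0.535 and 0.0593). Members were the neutrophil calcium-binding genes S100A8 (2.76, SE 1.28), S100A9 (2.23, SE 0.99) and S100A12 (2.98, SE 1.35) at the effector site, where S100A9 lay above background on 1 and S100A12 on 2 of 3 control arrays. Antimicrobial proteins had medians of -0.03 and 0.33 (adjusted p = 0.621 and 0.114), enteroendocrine genes of -0.39 (12 of 13 negative) and -0.56 (adjusted p = 0.0602 and 0.217), B cell genes of -0.19 and 0.16 (adjusted p = 0.181 and 0.463) and enterocyte genes of -0.27 and 0.0029 (adjusted p = 0.265 and 0.76). On the slide that holds both conditions the medians at the 2 sites were 0.11 and 0.15 for interferon-stimulated, 0.01 and -0.33 for neutrophil, -0.08 and 0.07 for antimicrobial, -2.42 and -0.65 for enteroendocrine, 0.53 and -0.08 for B cell and -0.62 and 0.73 for enterocyte genes. With slide as a block RSAD2 was 0.38 and 0.29 at the 2 sites, IFIT3 0.32 at the inductive and OASL 0.16 at the effector site, and the neutrophil medians were 0.08 and 0.28. S100A8 at the effector site was 4.31 on the shared slide and 4.14 with the block (adjusted p = 0.601), and S100A9 and S100A12 were 3.29 and 5.01 with the block (adjusted p = 0.619 and 0.486) and not above background on the control array of the shared slide. Without infected inductive replicate 3 the interferon median was -0.20 at the inductive site (adjusted p = 0.0236), and without control effector replicate 1 the enterocyte median was 0.66 at the effector site (adjusted p = 0.00738). With slide as a block, enteroendocrine genes were called lower at both sites (-1.59, adjusted p = 4.81e-06, and -1.25, adjusted p = 9.39e-06) and cell cycle genes higher at the inductive site (1.05, adjusted p = 1.83e-15), values whose mean over the sites rests on 1 piglet against 1. These calls are at the preset correlation. An estimated correlation was not used with the block, and without the block it gave these lists adjusted p = 0.846, 0.718 and 0.882. The remaining lists, for apoptosis, oxidative phosphorylation, bile acid and lipid handling, stem and crypt cells, adipocytes and reference genes, were not called in any of the 5 comparisons.

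Single members of lists that were not called differed between the sites. The antimicrobial list had medians of -0.02 in controls and -0.54 in infected piglets, while its member DEFB1, an epithelial defensin, was higher at the inductive site (3.83, SE 0.63, adjusted p = 0.00617, and 4.22, SE 0.63, adjusted p = 0.00463), as were NOS2 (2.07, SE 0.30, and 1.56, SE 0.30) and PGLYRP1 (3.03, SE 0.47, and 1.59, SE 0.47). The hormone-sensitive lipase LIPE was higher there too (1.38, SE 0.23, and 1.25, SE 0.23) and the crypt gene PROM1 lower (-2.0, SE 0.36, and -2.04, SE 0.36).

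Median, mean and test differed in sign for some lists. Among them were cytotoxic lymphocytes for infection at the inductive site (median 0.05, mean -0.06, tested as higher), B cells at the effector site (0.16, -0.14, tested as lower), enterocytes at the effector site (0.0029, 0.19, tested as lower), macrophages at the effector site (0.03, -0.01, tested as lower), bile acid and lipid handling at the effector site (-0.04, 0.21, tested as higher), goblet cells in the interaction (0.07, -0.08, tested as lower) and the antimicrobial list for site in controls (-0.02, 0.34, tested as higher). None of these was called.

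The infection differences at the 2 sites correlated across probes at r = 0.625, where probes are not independent replicates, and the other 9 groupings of the piglets gave 0.303 to 0.636. With an unadjusted p under 0.05 at both sites there were 698 probes (84 to 873 in the other groupings), and 98% of them had the same sign (86.5% to 99.2%). The share of probes higher in infected piglets was 59.4% in the dimmest, 52.9% in the middle and 46% in the brightest of 3 equal sets of probes at the inductive site and 59.2%, 50.3% and 44.3% at the effector site.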
